A study of Mus musculus with 16 samples.

How the data were processed

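RNA was measured on 16 Affymetrix mouse genome expression arrays, 1 per culture of P19CL6 cells, in 6 groups set by the labels: growth and days 4, 6, 8, 10 and 12 in medium with 1% DMSO. Per the labels, growth cells were passaged every 48 h, the differentiation medium was changed every 48 h, and the samples of a group were independent. Per the labels, the deposited values come from GCRMA, which subtracts background by probe sequence, normalizes arrays by quantiles and summarizes the probes of a probe set. The labels state neither a scale or base of the logarithm nor a software version. The values lay between 0.86 and 15.9 on all arrays, a range from which they were read as log2 intensities, and they were used as deposited.

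The table held 45101 probe sets. Of these, 34945 named a single gene, 932 named several, 9160 carried no gene name here and 64 were Affymetrix controls. The single-gene probe sets named 18193 genes. The Entrez identifiers of 34741 of them were found in the RefSeq table, and 0 symbols were updated from it. Probe sets above a log2 value of 4 on fewer than 2 arrays were left out as dim, 2 being the smallest group size. For each gene the single-gene probe set with the highest mean over all arrays was kept, which left 10802 genes. Probe sets that name several genes or none entered no comparison of genes and are described apart. Some probe sets of close paralogs, such as those of the myosins, actins, keratins and globins, can bind each other's transcripts, and an alternative left out the probe sets whose names end in _x_at or _s_at.

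A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual and 3.53 prior degrees of freedom). Replicate letters recur across the groups, but the labels do not say that a letter marks a shared culture or day, so no block was used in the fit reported first. Contrasts compared each DMSO day with growth, each day with the one before it, and day 12 with day 4. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, over all genes of the contrast, and a difference of at least 1 log2. A moderated F test over the 5 contrasts with growth called genes at the same adjusted p and a range of group means of at least 1 log2.

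The gene lists, 22 in number, were pluripotency, primitive streak and mesendoderm, cardiac transcription factors and progenitors, sarcomere, cardiac channels with calcium handling and hormones, smooth muscle, skeletal muscle, endothelium and blood, epicardium, extraembryonic and definitive endoderm, neural, mesenchyme and extracellular matrix, epithelium, cell cycle, Wnt signalling, BMP and TGF-beta signalling, Hox genes, Polycomb and DNA methylation, glycolysis, fatty acid and oxidative metabolism, imprinted genes, and stress and p53 response. Each was tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, for each of the 5 DMSO days against growth, with adjustment over all 110 pairs of a list and a day. The same test with a correlation estimated from the data, and limma's fry, which asks whether the members of a list move on balance one way, were run beside it. Members called up or down are counted with adjustment over all genes and adjusted over the list alone. Between days the members were only counted.

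Genes are named by a fixed rule. For each day against growth these are the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap between the groups, after values under 4 are set to 4, and for the other contrasts the 5 largest each way. Chance gives such non-overlap to 10% of genes for 3 arrays against 3 and to 20% for 3 against 2. Up to 4 called members of each list described, and 27 markers, of which 25 were analysed and 22 tested, complete the rule. Where all arrays of a group lay under 4 the group is called dim, and the fold was computed from the mean of the brighter group over 4 and given as at least that. The groups, contrasts, thresholds, lists, naming rule and alternatives were fixed before the data were examined, except where a later choice is named.

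RNA quality was described by the log2 difference between the 3′ and 5′ control probe sets of Actb and Gapdh. Means of 9 hybridization, 12 poly-A and 3 18S rRNA control probe sets were compared between groups of arrays by two-sided exact permutation tests, 15 in number, with Benjamini-Hochberg adjustment. Only the Actb and Gapdh differences of growth and DMSO arrays were in the plan. The other control means, and the comparisons of day 12 and of letter A with other arrays, were not.

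The alternatives were no dim filter, a stricter one of log2 6, quantile normalization again, scaling to a common median, values under 4 set to 4, a variance trend with robust estimation, array weights, a replicate block, a fit of only the groups compared, all probe sets, the mean of a gene's probe sets, the omission of _x_at and _s_at probe sets, the adjusted p alone, and each array left out in turn. A fit to the arrays of letters B and C was added after the data were seen. The method was tested on simulated data with 200 changed genes among 10802. At a made change of 1.5 log2, 70 to 90% of genes were recovered in the 10 contrasts, with 2 to 8 false calls per contrast, and 5 of 5 shifted and 0 of 95 unshifted pairs of a list and a contrast were called. The simulated genes varied independently of each other, so the list result cannot show whether the preset correlation is large enough for the real data. Overlaps of the called genes between days were compared with the product of their shares and with 20 simulations of unchanged groups. In these, genes were called at the same thresholds, or as many genes as were called were taken by t, a comparison added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.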

Results

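Expression was measured in P19CL6 cells, a mouse embryonal carcinoma line that forms cardiac muscle in medium with dimethyl sulfoxide (DMSO). The samples were 3 cultures kept in growth without DMSO by passage every 48 h, and cultures taken after 4, 6, 8, 10 and 12 days in medium with 1% DMSO. Days 4, 8 and 10 had 3 arrays each, and days 6 and 12 had 2 each, so that 16 arrays were compared. The table held 45101 probe sets on the log2 scale, of which 39.6 to 42.5% lay above the dim cutoff of 4 on each array. Array medians ran from 3.16 to 3.27. After filtering, 10802 genes were tested, each by 1 probe set. Values below are mean log2 signal ± SD with n = 3 for growth and days 4, 8 and 10 and n = 2 for days 6 and 12, and the number of arrays limits their precision. A group with every array under the cutoff is called dim, and a fold against it is given as a lower bound. The series holds no culture kept as long without DMSO, so the effect of DMSO cannot be separated from that of time in culture without passage.

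Arrays of a group correlated at 0.956 or more over the tested genes, and the lowest correlation between any 2 arrays was 0.723. The first principal component held 53.3% of the variance and ordered the groups by day, and the second held 23.6%. Day 8 replicate A stood apart from its group. It correlated at 0.990 to 0.992 with the 2 day 6 arrays and at 0.956 to 0.967 with day 8 replicates B and C. The counts of genes called in contrasts with day 8, most day 8 lists and some day 8 genes are therefore also given without this array. This alternative was chosen among the planned ones after the array's position was seen. All arrays share 1 estimate of the spread, so day 8 replicate A also affects contrasts without day 8. When it was left out, 756 genes were called from day 4 to day 6, against 662. From day 10 to day 12 the number was 381, against 331. In the control probe sets of RNA integrity the 3′ minus 5′ difference of Actb was 0.88 ± 0.18 log2 on 13 DMSO arrays and 0.91 ± 0.04 on 3 growth arrays (two-sided exact permutation p = 0.745), and that of Gapdh was -0.30 ± 0.07 and -0.33 ± 0.03 (exact p = 0.536). The 18S rRNA control probe sets were at 6.46 ± 0.99 on the DMSO arrays and 5.24 ± 0.38 on the growth arrays (exact p = 0.05, 0.1875 after adjustment over 15 tests), and the mean of each DMSO day, 5.83 to 8.37, lay above that of growth.

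**Figure D1:**
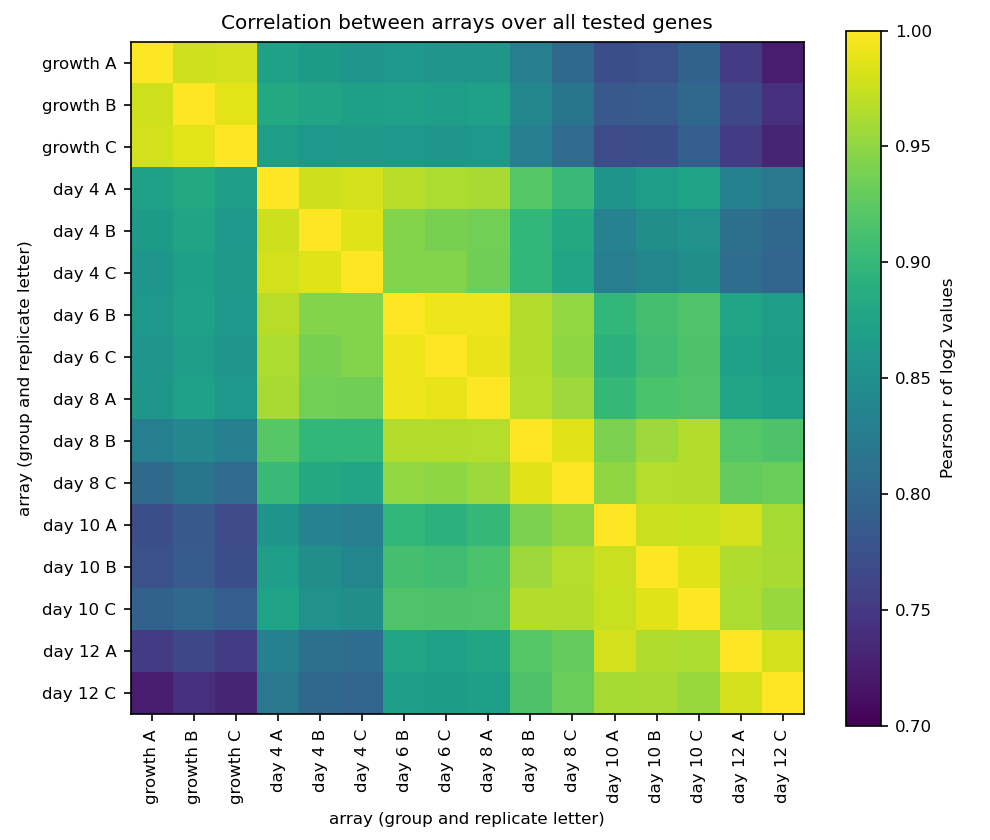
Pearson correlation of log2 values over the 10802 tested genes between each pair of the 16 arrays, with group and replicate letter on both axes and colour for r. Day 8 replicate A lies at 0.990 to 0.992 with the day 6 arrays and at 0.956 to 0.967 with the other arrays of its own day.

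Each DMSO day was compared with growth to find which genes differ after that time in DMSO. The number of genes called rose from 2914 at day 4 to 4524 at day 12, with 2898 at day 6, 3349 at day 8 and 4107 at day 10. At day 4, 1442 genes were higher and 1472 lower than in growth, and at day 12 the numbers were 2435 and 2089. The median change over all genes was within 0.05 log2 of 0 in every comparison. Normalization by quantiles brings the arrays to like distributions, so this value is largely set by the processing.

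**Figure D2:**
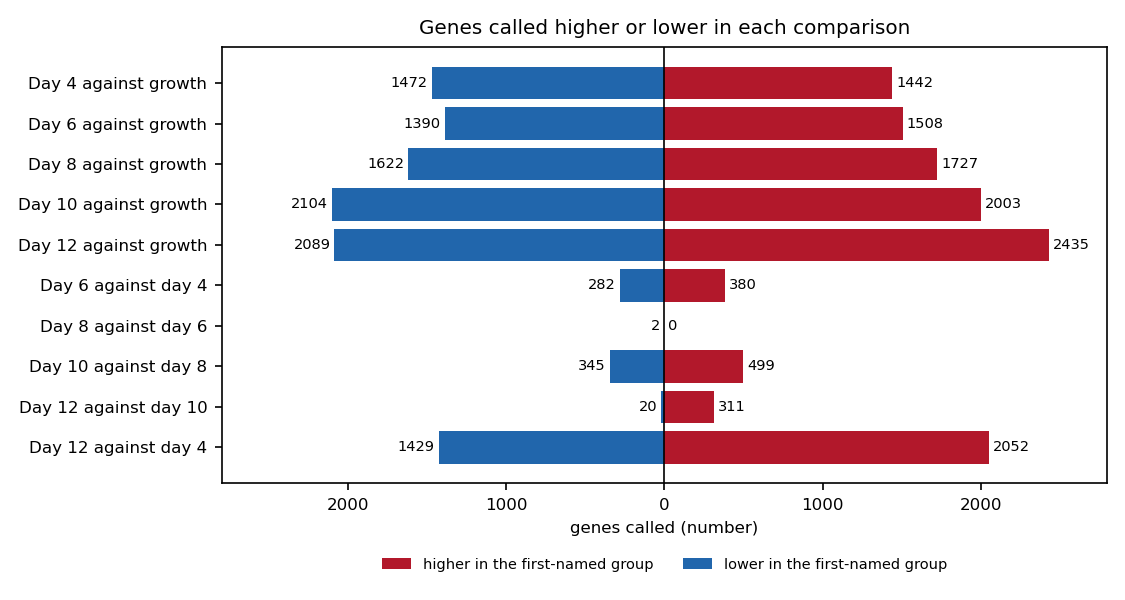
Number of genes called higher (to the right) or lower (to the left) in the group named first, for 5 comparisons of a DMSO day with growth and 5 between days, at an adjusted p under 0.05 and a difference of at least 1 log2. Day 8 against day 6 has 2 genes and day 12 against day 10 has 311 rises and 20 falls.

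Genes of the primitive streak, the embryonic site where mesoderm forms, were among the largest rises at day 4. Mixl1 was at 11.99 ± 0.69 against 2.39 ± 0.30 in growth (at least 254-fold higher, adjusted p = 2.02e-11), and Mesp1, a regulator of the earliest cardiac mesoderm, was at 11.89 ± 1.14 against 2.82 ± 0.29 (at least 238-fold). The retinoic acid hydroxylase Cyp26a1 was at least 297-fold higher, the apelin receptor Aplnr at least 179-fold, and Asb4 at least 337-fold, from 2.50 ± 0.13 to 12.40 ± 0.35. The other 5 of the 10 largest rises were Klhl6, Cited2, Cdh2, Lgals3 and Cdh11, at 116-fold or more. The 10 largest falls held the pluripotency genes L1td1 (fell by 6.81 ± 0.33 log2, SE), Utf1 (fell by 5.40), Gdf3 (at least 35.7-fold lower) and Eras (at least 34.6-fold lower), the Nodal antagonist Lefty1 (fell by 6.04), and Gng3, Enpp3, Tnnt1, Npy and Pim2.

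Of the 20 tested members of the primitive streak and mesendoderm list, 16 rose at day 4 and 2 fell, Lefty1 and Fgf5, with the same numbers adjusted over the list alone (adjusted p = 7.74e-07, and adjusted p = 0.282 with an estimated correlation). Snai1, a repressor of E-cadherin, was at 10.39 against 2.92. Pluripotency members fell: 14 of 20 were lower and 1, Klf4, was higher (14 and 2 adjusted over the list alone, adjusted p = 3.62e-06, and adjusted p = 0.112 with an estimated correlation). Pou5f1 went from 14.30 ± 0.19 to 11.23 ± 1.16, Nanog from 7.89 ± 0.43 to 3.89 ± 0.43 and Sox2 from 10.87 ± 0.41 to 8.30 ± 0.56. In the BMP and TGF-beta list 18 of 25 rose and 1 fell, also over the list alone (adjusted p = 5.91e-09, and adjusted p = 0.0855 with an estimated correlation). Its largest rises were Msx1 (at least 116-fold), Id1 (11.58 against 5.24), Msx2 and Bmp4 (10.33 against 4.87), the ligand and 3 genes known as targets of BMP signalling. Wnt signalling members rose in 12 of 26 and fell in 2, also over the list alone (adjusted p = 0.0045, and adjusted p = 0.112 with an estimated correlation), led by Rspo3, Dkk1 (at least 38.7-fold), Wnt5a and Axin2 (10.03 against 5.90).

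Hox genes, regulators of position along the body axis, were part of the day 4 rise. In all, 10 of 20 tested Hox genes rose and 0 fell, also over the list alone (adjusted p = 0.000159, and adjusted p = 0.0855 with an estimated correlation), among them Hoxb2 at 8.42 against 1.66 (at least 21.5-fold) and Hoxd9 at 10.29 against 2.98. Epithelial genes mostly fell: 9 of 15 were lower and 1, the desmosome gene Dsp, was higher (11 and 1 over the list alone, adjusted p = 0.0033, and adjusted p = 0.276 with an estimated correlation), with Epcam at 8.40 against 12.14 and the splicing factor Esrp1 at least 8.26-fold lower. Neural members fell in 6 of 10 and rose in 0, also over the list alone (adjusted p = 0.0191, and adjusted p = 0.217 with an estimated correlation), led by Otx2 at 6.62 against 10.68. Stress and p53 genes fell in 7 of 17 and rose in 0, also over the list alone (adjusted p = 0.0157, and adjusted p = 0.371 with an estimated correlation), with Trib3 at 7.35 against 11.32 and Atf3 at 4.24 against 7.53. In the sarcomere list 2 of 26 rose and 2 fell (1 and 1 over the list alone, adjusted p = 0.843, and adjusted p = 0.939 with an estimated correlation).

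At day 6 the largest rise was that of Igf2, an imprinted growth factor, at 13.76 ± 0.15 against 5.24 ± 0.40 (367-fold, adjusted p = 1.93e-07). The mesenchymal genes Cdh11 (at least 165-fold), Snai2 (at least 157-fold) and Nrp1 (at least 108-fold), the cardiac mesoderm factor Hand1 (at least 94.8-fold) and Bmp4 (83.4-fold) were among the 10 largest, with Ahnak, Lgals3, Stard8 and Pmp22. L1td1 was at least 158-fold lower, Utf1 fell by 7.05 and Otx2 by 6.66 log2. Cited1 was also among the 10 largest falls, with Lefty1, Gng3, Pim2, Enpp3, Tnnt1 and Npy. Cardiac transcription factors and progenitor genes rose in 14 of 24 and 2, Tbx1 and Foxh1, fell, also over the list alone (adjusted p = 6.4e-05, and adjusted p = 0.112 with an estimated correlation). Tbx20 was at 9.73 against 2.60, Smarcd3 at 10.19 against 3.27 and Isl1 at 8.37 ± 0.18 against 2.13 ± 0.32. Imprinted genes rose in 10 of 14 and fell in 2 (10 and 3 over the list alone, adjusted p = 0.0017, and adjusted p = 0.224 with an estimated correlation). Extracellular matrix and mesenchyme members rose in 11 of 27 and fell in 0, also over the list alone (adjusted p = 0.000122, and adjusted p = 0.217 with an estimated correlation), including Fn1 at 12.08 against 7.52. Hox genes reached their highest number, 13 of 20, also over the list alone (adjusted p = 2.16e-07, and adjusted p = 0.0855 with an estimated correlation). The Wnt list (11 of 26 up, 1 down, adjusted p = 0.0395, and adjusted p = 0.224 with an estimated correlation) was no longer called without growth replicate B or C or day 6 replicate B, with adjusted p up to 0.0926. The calls of Tnnt2, Acta2, Col1a1 and Ryr2 (higher) and Eomes (lower) at this day were lost without 1 or the other of the day 6 arrays, with adjusted p up to 0.0984, 0.133, 0.172, 0.0713 and 0.101 in that order. The changes were then 2.62 to 3.41 log2 for Acta2 and -1.35 to -1.20 for Eomes. Growth was dim for the others, whose rises over the cutoff were at the lowest 1.60 for Tnnt2, 0.30 for Col1a1 and 0.51 for Ryr2, against 1.91, 0.68 and 0.68 with all arrays.

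Of the 26 tested sarcomere genes, 5 were called higher than growth at day 6 and 15 at day 8, where 10 were called that had not been at day 4 or 6 (12 without day 8 replicate A). Levels differed between the day 8 arrays. Tnni1, the slow skeletal troponin I of the embryonic heart, was at 11.42 ± 1.76 against 2.64 ± 0.34 in growth (at least 172-fold, adjusted p = 7.66e-08), and Tnnt2 was at 8.57 ± 2.39 against 2.99 ± 0.04 (at least 23.7-fold). Without replicate A these means were 12.44 and 9.84. Igf2 was 395-fold higher, and Ahnak, Snai2 (at least 201-fold), Nrp1, Pmp22, Capn6, Cdh11, Dlk1 (at least 87.0-fold, from 10.44 ± 2.33, or 11.79 without replicate A) and Rbms3 completed the 10 largest rises. Pou5f1 fell by 6.79 ± 0.53 log2 (SE) and Utf1 by 8.28, and the other large falls were Lefty1, Cited1, L1td1, Pim2, Gng3, Otx2, Tdgf1 and Enpp3. In the sarcomere list 15 of 26 rose and 1, Tnnt1, fell (17 and 1 over the list alone, adjusted p = 0.0055, and adjusted p = 0.482 with an estimated correlation). Pluripotency members fell in 16 of 20 and rose in 2, also over the list alone (adjusted p = 6.46e-08, and adjusted p = 0.0855 with an estimated correlation). Cardiac transcription factors rose in 15 of 24 and fell in 2, also over the list alone (adjusted p = 9.27e-06, and adjusted p = 0.0859 with an estimated correlation). Cell cycle members fell in 16 of 33 and rose in 1, Ccne2, also over the list alone (adjusted p = 2.11e-05, and adjusted p = 0.369 with an estimated correlation), led by the mitotic kinases Plk1 (8.88 against 11.03) and Aurka (8.60 against 10.68). Without replicate A, 3613 genes were called at day 8, 1871 higher and 1742 lower, and 3166 of the 3349 calls were shared. Of 102 calls of named genes at day 8, 101 were kept, and Pou5f1 was 6.76 and Utf1 8.24 log2 lower than growth. The lists then gave 17 of 26 sarcomere genes up and 1 down, 17 of 20 pluripotency genes down and 2 up, 18 of 33 cell cycle genes down and 1 up, and 15 of 24 cardiac factors up and 2 down (adjusted p = 2.65e-06, 1.43e-07, 4.48e-08 and 1.62e-06, and adjusted p = 0.0984, 0.0984, 0.0244 and 0.0387 with an estimated correlation). The rise of Hbb-bh1 at day 8 (9.18 against 3.22) was no longer called without replicate B or C (adjusted p up to 0.0548, and at least 3.98 log2 over the cutoff), and without replicate A its mean was 12.29. The calls of Myh6, Myh7 and Actc1 were lost without replicate C, and those of Myh6 and Myh7 also without replicate B or some growth arrays, with adjusted p up to 0.208, 0.123 and 0.0666. Growth was dim for these genes. Their rises over the cutoff were at the lowest 0.24, 0.97 and 0.45 log2, against 1.16, 1.71 and 1.03 with all arrays. Without replicate A each was called (adjusted p = 0.001, 5.69e-05 and 0.000146).

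At day 10, 5 of the 10 largest rises were those of contractile genes. Tnni1 was at 13.67 ± 0.02 (at least 815-fold above growth), Tnnt2 at 13.04 ± 0.21 (at least 528-fold), the atrial light chains Myl7 at 14.30 ± 0.22 against 4.56 ± 0.68 (854-fold) and Myl4 at 12.40 ± 0.31 (at least 339-fold), and cardiac actin Actc1 at 12.04 ± 0.17 (at least 263-fold). The embryonic globin Hbb-bh1 was at 12.86 ± 0.33 (at least 464-fold, adjusted p = 0.000268), and Hand2, Igf2, Dlk1 and Igfbp5 were the others of the 10 largest rises. Utf1 was at least 290-fold lower, Pou5f1 fell by 6.39 log2 to 7.91 ± 0.76, and L1td1, Lefty1, Pim2, Otx2, Etv5, Cited1, Slc7a7 and Enpp3 were the others of the 10 largest falls. Of 26 tested sarcomere genes, 24 rose and 1, Tnnt1, fell, also over the list alone (adjusted p = 2.6e-09, and adjusted p = 0.183 with an estimated correlation, or 5.45e-12 and 0.0324 without day 8 replicate A). Cardiac factors rose in 20 of 24 and fell in 2, also over the list alone (adjusted p = 6.32e-08, and adjusted p = 0.0855 with an estimated correlation, or 2.46e-08 and 0.0294 without day 8 replicate A). Nkx2-5 was at 4.75 ± 0.75 and Tbx5 at 4.56 ± 0.67, both dim in growth. Channel and calcium handling genes rose in 12 of 20 and fell in 3, also over the list alone (adjusted p = 0.0027, and adjusted p = 0.252 with an estimated correlation, or 0.0011 and 0.1426 without day 8 replicate A). Phospholamban, Pln, a regulator of calcium uptake, was at 9.91 against 2.99 and the ryanodine receptor Ryr2 at 7.26 ± 0.40 against 3.07 ± 0.04. Endothelium and blood genes rose in 6 of 15 and fell in 2, also over the list alone, without a call for the list (adjusted p = 0.0917, and adjusted p = 0.386 with an estimated correlation, or 0.0218 and 0.1227 without day 8 replicate A). They included Hba-x (at least 216-fold), Hbb-y and the receptor Tek, at 8.00 against 2.96.

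At day 12 the 10 largest rises were muscle genes and imprinted genes. Tnnt2 reached 14.07 ± 0.14 against 2.99 ± 0.04 in growth (at least 1072-fold, adjusted p = 1.91e-07), Actc1 13.86 ± 0.09 (at least 927-fold), Myh6, the alpha myosin heavy chain, 13.73 ± 0.17 (at least 850-fold), Myl4 13.67 ± 0.10 (at least 814-fold) and Myl7 14.70 ± 0.01 (1124-fold). Tnni1 was at least 590-fold higher, the smooth muscle genes Acta2 and Myl9 were 477-fold and 463-fold higher, Dlk1 was at least 771-fold higher and Igf2 553-fold. The 10 largest falls were Utf1 (fell by 7.32 log2), L1td1, Gng3, Enpp3, Slc7a7, Cited1, the DNA methyltransferase Dnmt3b (fell by 5.73), Nodal (fell by 5.56), Lin28a and Tcfl5. On the 2 day 12 arrays the 18S rRNA control probe sets were at 8.37 ± 0.46 against 5.93 ± 0.62 on the other 14 arrays, and the poly-A spike-in probe sets at 6.51 ± 0.62 against 4.97 ± 0.45. For both, the two-sided exact permutation p was 0.0083, the smallest that 120 arrangements can give, and 0.0417 after adjustment over 15 tests. The comparison of day 12 with the other arrays was not planned.

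Sarcomere genes rose in 24 of 26 at day 12 and 1, Tnnt1, fell, also over the list alone (adjusted p = 7.77e-10, and adjusted p = 0.183 with an estimated correlation). The beta myosin heavy chain Myh7 was at 6.88 ± 1.07 and the ventricular light chain Myl2 at 5.79 ± 1.19, against 3.58 ± 0.27 and 2.30 ± 0.01 in growth. Cardiac transcription factors rose in 21 of 24 and fell in 2, Tbx1 and Foxh1, also over the list alone (adjusted p = 1.53e-07, and adjusted p = 0.0855 with an estimated correlation). Nkx2-5 was at 5.93 ± 0.57, Gata4 at 9.56 ± 0.47, Tbx5 at 5.62 ± 0.22 and Mef2c at 9.07 ± 0.33. Channels and calcium handling genes rose in 15 of 20 and fell in 2, also over the list alone (adjusted p = 0.000159, and adjusted p = 0.183 with an estimated correlation). The risers included Pln, Ryr2 at 9.31 ± 0.22, triadin (Trdn, 8.70 against 2.50) and the sodium-calcium exchanger Slc8a1 (8.00 against 2.52), and the fallers were Cacna1g and Kcnj3. Smooth muscle genes rose in 10 of 13 and fell in 0, also over the list alone (adjusted p = 0.0013, and adjusted p = 0.241 with an estimated correlation). In the skeletal muscle list 3 of the 22 genes on the array passed the filter and 2, Myl1 (8.42 against 3.01) and Pygm, rose, also over the list alone, without a call for the list (adjusted p = 0.0845).

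Markers of other lineages were also higher at day 12, on the arrays whose control probe sets differed, but part of these rises came earlier. The endoderm list was called higher on each earlier day (adjusted p = 0.0324, 0.0087, 0.0042 and 0.000938 at days 4, 6, 8 and 10). The epicardium list was also called at day 10 (adjusted p = 0.0086). With an estimated correlation none of these was called. Bnc1, Upk3b and Ttr were already called higher at day 8, at 10.19, 8.47 and 8.76 without replicate A. At day 12 all 11 tested epicardium genes rose, also over the list alone (adjusted p = 6.21e-07, and adjusted p = 0.0855 with an estimated correlation), among them Bnc1 (11.36 against 2.80), Upk3b (10.55 against 2.03), Wt1 (8.33 against 3.13) and Tbx18 (7.86 against 2.56). Endoderm genes rose in 11 of 13 and fell in 0, also over the list alone (adjusted p = 0.000189, and adjusted p = 0.202 with an estimated correlation), with the serum proteins Ttr at 9.74, Afp at 9.12 ± 0.19, Rbp4 at 8.49 and Apoa1 at 7.87, against 2.77 to 3.64 in growth. The array named 14 epicardium and 23 endoderm genes, and those not tested did not pass the dim filter. A gene bright only at day 12 passes it, so these shares lean towards rises. Each of the 27 tested extracellular matrix and mesenchyme genes rose, also over the list alone (adjusted p = 7.01e-12, and adjusted p = 0.0855 with an estimated correlation), led by Col3a1 at 12.16 against 2.85 (at least 286-fold). Col1a1 was at 4.28 and 6.41 on the 2 arrays against 3.11 ± 0.09. Endothelium and blood genes rose in 6 of 15 and fell in 2, also over the list alone, without a call for the list (adjusted p = 0.253). Pecam1 (4.12 ± 0.70 against 2.82 ± 0.35) was not called without growth replicate B or C or day 12 replicate C (adjusted p up to 0.239). Over the cutoff its rise was at least 0.31 log2, and 0 to 0.61 without 1 array. Hba-x was not called without any 1 growth or day 12 array (adjusted p up to 0.119), and over the cutoff its rise was then at least 2.76 log2. The neural list had 2 of 10 up, Map2 and Ncam1, and 5 down, also over the list alone, without a call (adjusted p = 0.309). Epithelial genes rose in 4 of 15 and fell in 7, also over the list alone (adjusted p = 0.395), with Dsp at 11.49 against 5.52 and Epcam at 6.97 against 12.14. Myod1, a skeletal muscle regulator, Pax6, a neural regulator, and the atrial hormone gene Nppa were dim on all 16 arrays and were not tested.

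Cell cycle genes fell in 26 of 33 at day 12 and 1, Ccne2, rose, also over the list alone (adjusted p = 1.68e-08, and adjusted p = 0.263 with an estimated correlation), with Plk1 at 7.92 against 11.03. Mki67 stayed bright, at 10.26 ± 0.18 against 11.05 ± 0.05, a difference under the 1 log2 threshold. Pluripotency genes fell in 17 of 20 and rose in 2, Klf2 and Klf4, also over the list alone (adjusted p = 2.18e-07, and adjusted p = 0.0855 with an estimated correlation). Pou5f1 was at 9.21 ± 1.02, Nanog at 3.48 ± 0.93 and Sox2 at 8.38 ± 0.27. Polycomb and DNA methylation genes fell in 8 of 20 and rose in 3 (9 and 3 over the list alone), without a call for the list (adjusted p = 0.0519, and down to 0.0382 when 1 of 6 arrays was left out). At day 10 the list was called (adjusted p = 0.0404, and adjusted p = 0.299 with an estimated correlation), but not without growth replicate A or day 10 replicate A (up to 0.0584). The largest fall was that of Cbx7 (at least 22.1-fold lower), and Phc1 went from 12.35 to 8.84, Dnmt3a from 11.03 to 8.25, and Bmi1 rose from 6.28 to 9.56. Glycolysis genes rose in 9 of 18 and fell in 0, also over the list alone (adjusted p = 0.0016, and adjusted p = 0.263 with an estimated correlation), led by the regulators Pfkfb3 (8.77 against 4.64) and Pdk1 (11.25 against 8.61). Fatty acid and oxidative metabolism genes rose in 9 of 19 and 1, Cpt2, fell, also over the list alone (adjusted p = 0.0127, and adjusted p = 0.297 with an estimated correlation). The fatty acid transporter Cd36 was at 9.04 against 2.90, the muscle cytochrome oxidase subunit Cox6a2 at 8.35 against 4.35 and the coactivator Ppargc1a at 7.33 against 3.26. Imprinted genes rose in 10 of 14 and 1, Snrpn, fell, also over the list alone (adjusted p = 0.0031, and adjusted p = 0.241 with an estimated correlation). BMP and TGF-beta genes rose in 20 of 25 and fell in 1, also over the list alone (adjusted p = 1.26e-06, and adjusted p = 0.103 with an estimated correlation), with Id2 at 12.40 and Bambi at 12.69. Wnt genes rose in 11 of 26 and fell in 1, Axin2, also over the list alone, without a call (adjusted p = 0.0876). The stress and p53 list had 6 of 17 up and 6 down, also over the list alone (adjusted p = 0.818). Of the primitive streak and mesendoderm list 1 of 20, Pdgfra, rose and 5 fell, also over the list alone (adjusted p = 0.174), and Hox genes rose in 6 of 20 and fell in 0, also over the list alone (adjusted p = 0.0519, and down to 0.0275 when 1 of 6 arrays was left out).

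Over the 5 days, 61 of 110 pairs of a list and a day were called, 13 at day 4, 10 at day 6, 10 at day 8, 15 at day 10 and 13 at day 12. With a correlation estimated from the data and all arrays fitted, 0 pairs were called, and the lowest adjusted p was 0.0855. Without day 8 replicate A this test called the cell cycle and cardiac factor lists at days 8 and 10 (adjusted p = 0.0244 to 0.0387). It also called the sarcomere and extracellular matrix lists at day 10 (adjusted p = 0.0324 and 0.0343), and no other list at these days. With fry, 1 of the 61 calls ended and 22 were added. In 6 pairs the median, the mean and the test at the preset correlation differed in sign, and 0 of these were called.

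**Figure D3:**
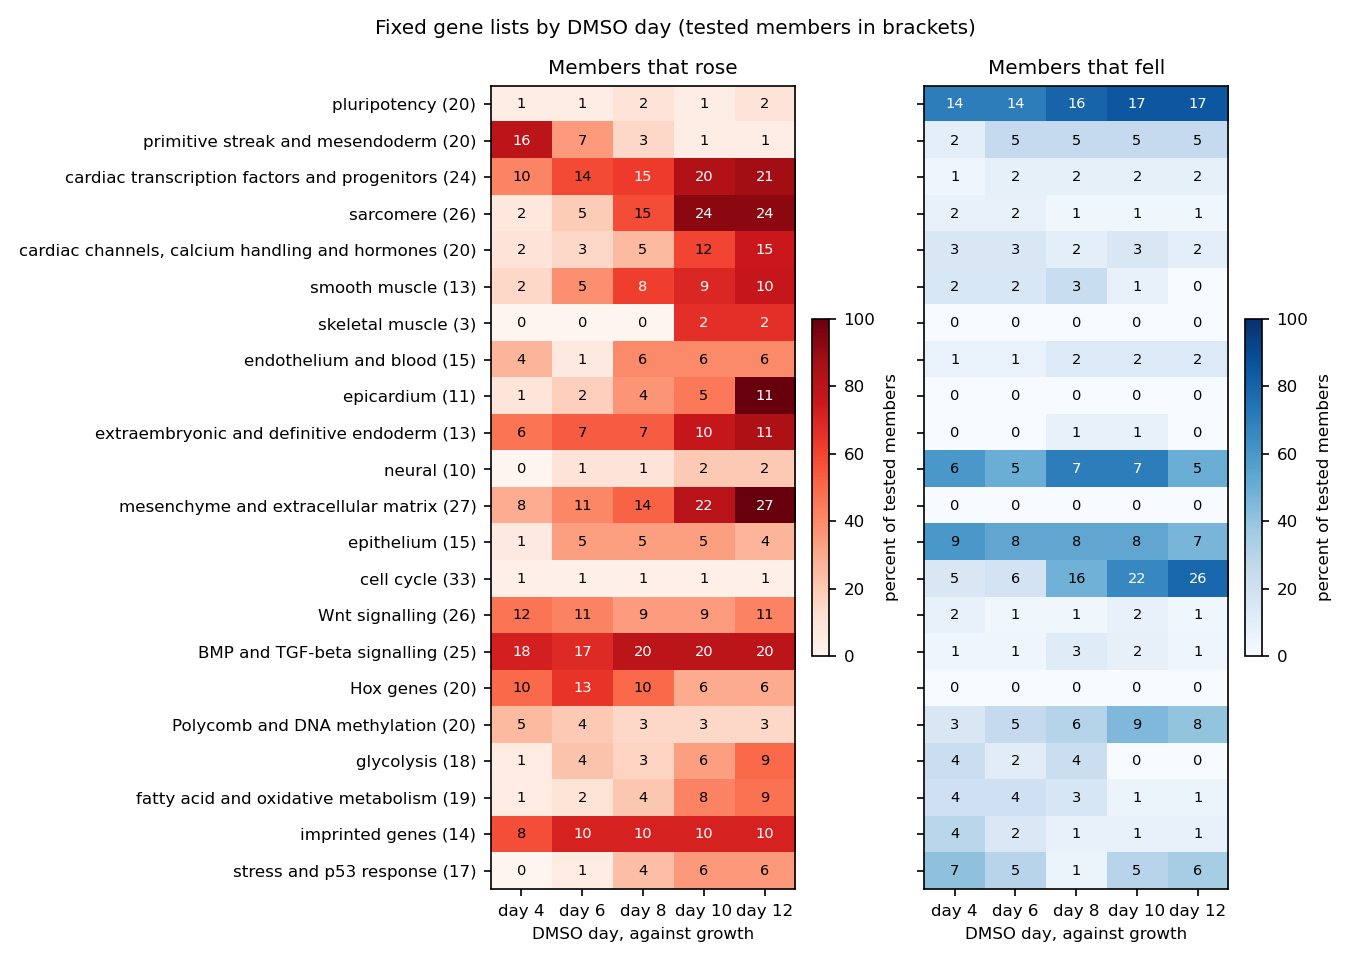
Number of tested members of each of the 22 fixed gene lists called higher (left panel) or lower (right panel) than in growth on each DMSO day, with colour for the percent of tested members. Rises of the sarcomere list go from 2 of 26 at day 4 to 24 at days 10 and 12, and falls of the cell cycle list from 5 of 33 to 26.

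Consecutive days were compared to place the changes in time. From day 4 to day 6, 662 genes changed, 380 up and 282 down. The primitive streak genes fell back: Mixl1 fell by 8.27 ± 0.31 log2 (SE) to 3.72 ± 0.48, Mesp1 by 6.77, Lhx1 by 5.70 and Eomes by 5.17, and 12 of 20 list members fell and 0 rose (18 and 0 over the list alone). Dll3, a Notch ligand, was at least 34.2-fold lower. Snai2 rose from 5.61 ± 0.29 to 11.30 ± 0.02 (adjusted p = 1.07e-07), Ahnak, Tmem108, Ddah1 (at least 30.6-fold) and the keratin Krt18 were the others of the 5 largest rises, and 7 of 24 cardiac factors rose and 1 fell (10 and 1 over the list alone), including Mef2c, from 3.21 ± 0.28 to 6.88 ± 0.85, and Isl1. The number of genes was 309 without day 6 replicate C and 383 without replicate B, and 415 when only the groups compared were fitted.

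From day 6 to day 8, 2 genes were called by limma, both lower: the interferon regulator Irf1, at 6.18 ± 0.27 against 7.79 ± 0.15 (adjusted p = 0.00568), and Evx1, a streak gene, at 2.47 ± 0.21 against 4.47 ± 0.64 (adjusted p = 0.0461). Day 8 was dim for Evx1. After values under 4 were set to 4 its change was -0.47 log2, and -0.925 to -0.016 without 1 array. At an unadjusted p under 0.05 there were 1237 genes. Irf1 was not called without day 6 replicate B (adjusted p = 0.0696), nor Evx1 without day 6 replicate C or day 8 replicate B or C (up to 0.332). When day 8 replicate A was left out, 613 genes were called, 404 up and 209 down. The largest rises were then the embryonic globins Hbb-bh1, at 12.29 against 3.19 (adjusted p = 2.12e-08), and Hba-x, at 11.03 against 2.03, with Myl7 at 10.75 against 2.98, Adamts1 and Ror1. The largest falls were Cxcr4, Foxf1, Cyp26a1, Fst and Rgs5. In this setting 16 of 26 sarcomere genes rose and 0 fell, 6 of 24 cardiac factors rose and 2 fell, and 7 of 20 primitive streak genes fell and 0 rose.

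From day 8 to day 10, 844 genes changed, 499 up and 345 down, and sarcomere genes rose in 23 of 26 and fell in 0, also over the list alone. Actc1 rose from 4.66 ± 1.66 to 12.04 ± 0.17 (adjusted p = 5.49e-06), Myh6 from 4.85 ± 1.99 to 11.65 ± 0.59, Myl9 from 5.39 ± 1.23 to 10.99 ± 0.30 and Col3a1 from 4.09 ± 1.14 to 9.99 ± 0.36. Without day 8 replicate A the day 8 means were 5.54 for Actc1, 5.74 for Myh6, 6.06 for Myl9 and 4.63 for Col3a1. Myl7, from 8.26 ± 4.35 (10.75 without day 8 replicate A) to 14.30 ± 0.22, was not called without day 10 replicate A (adjusted p = 0.0506). Cardiac factors rose in 10 of 24 and fell in 0 (10 up and 1 down over the list alone), with the first rises of Nkx2-5 and Tbx5 between days, and channel and calcium genes in 10 of 20 (12 over the list alone). Tdo2, a tryptophan oxygenase, was at least 20.4-fold lower, and Lin28a (fell by 3.37), Myc (fell by 3.03), Ptgis and Lgals3 were the other large falls. Without day 8 replicate A Lin28a fell by 2.79 and Myc by 2.20, the largest rises were those of Actc1, Myh6, Pnoc, Col3a1 and Tnni3, and the largest falls those of Tdo2, Irx3, Cdh6, Lin28a and B4galnt2. In this setting the number of genes was 626, of which 572 were among the 844, and 20 of 26 sarcomere genes, 8 of 24 cardiac factors and 8 of 20 channel and calcium genes rose and 0 fell. Of 69 calls of named genes 56 were kept. It was 368 when only these days were fitted.

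From day 10 to day 12, 331 genes changed, and 311 of these, 94.0%, rose. The share was 83.4% (272 up, 54 down) without day 12 replicate A, 97.4% (151 up, 4 down) without replicate C and 83.8% (631 up, 122 down) with letters B and C. Afp, the fetal serum protein of yolk sac endoderm and liver, rose from 3.36 ± 0.86 to 9.12 ± 0.19 (adjusted p = 1.43e-07), and Tm4sf5, Tgm2, the sinus node factor Shox2 (5.87 ± 1.31 to 9.09 ± 0.16) and Enpep were the other large rises. The embryonic globin Hbb-y fell from 7.64 ± 1.31 to 3.83 ± 0.77, and Igsf11, Phlda2, Dpf3 and Cthrc1 also fell. Epicardium genes rose in 6 of 11 (7 over the list alone), endoderm genes in 1 of 13 (3 over the list alone), extracellular matrix genes in 9 of 27 (12 over the list alone, with 1 fall) and sarcomere genes in 7 of 26 (9 over the list alone), with 0 falls when adjusted over all genes. These rises fall on the arrays with the higher 18S rRNA and poly-A control signals. The number was 155 without day 12 replicate C, 480 without day 10 replicate A and 121 when only these days were fitted, and the falls of Dpf3, Cthrc1, Igsf11 and Phlda2 were not called without replicate C. That of Cthrc1 was not called without any 1 of the day 10 or day 12 arrays, nor that of Dpf3 without day 10 replicate B or C or day 12 replicate A (adjusted p up to 0.26). Over all these leave-outs the falls were at least 1.32 log2 for Dpf3, dim at day 12, and 1.35 for Cthrc1, 3.06 for Igsf11 and 2.09 for Phlda2, after values under 4 were set to 4.

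Day 12 was also compared with day 4, to set the latest day against the earliest in the same medium. Here 3481 genes changed, 2052 up and 1429 down. Tnnt2 (at least 1072-fold), Actc1, Myh6 (at least 850-fold), Myl4 and Dlk1 rose most, and Cyp26a1 (at least 297-fold lower), Mixl1, Mesp1, Aplnr and Eomes (fell by 7.24 ± 0.41 log2, SE) fell most. Primitive streak genes fell in 19 of 20 and rose in 0, sarcomere genes rose in 25 of 26 and fell in 0, epicardium genes rose in all 11, and cell cycle genes fell in 21 of 33 and rose in 0, each with the same numbers over the list alone. Fatty acid and oxidative metabolism genes rose in 13 of 19 and fell in 0, also over the list alone.

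Across the 6 groups 6575 genes differed by the F test and by at least 1 log2 between group means. Their highest mean was in growth for 2291 genes, at day 4 for 1070, at day 6 for 470, at day 8 for 331, at day 10 for 573 and at day 12 for 1840. The day 8 means include replicate A, which lay with the day 6 arrays, and these numbers were not recounted without it. The markers fixed in advance spread over this course. Eomes and Mesp1 were highest at day 4, at 11.70 ± 0.40 and 11.89 ± 1.14, and Isl1 at day 8, at 9.29 ± 0.90. Mef2c was highest at day 10, at 9.78 ± 0.13, and Tnnt2, Myh6, Actc1, Ryr2, Acta2 and Afp at day 12. The markers T and Hcn4 are not analysed here.

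**Figure D4:**
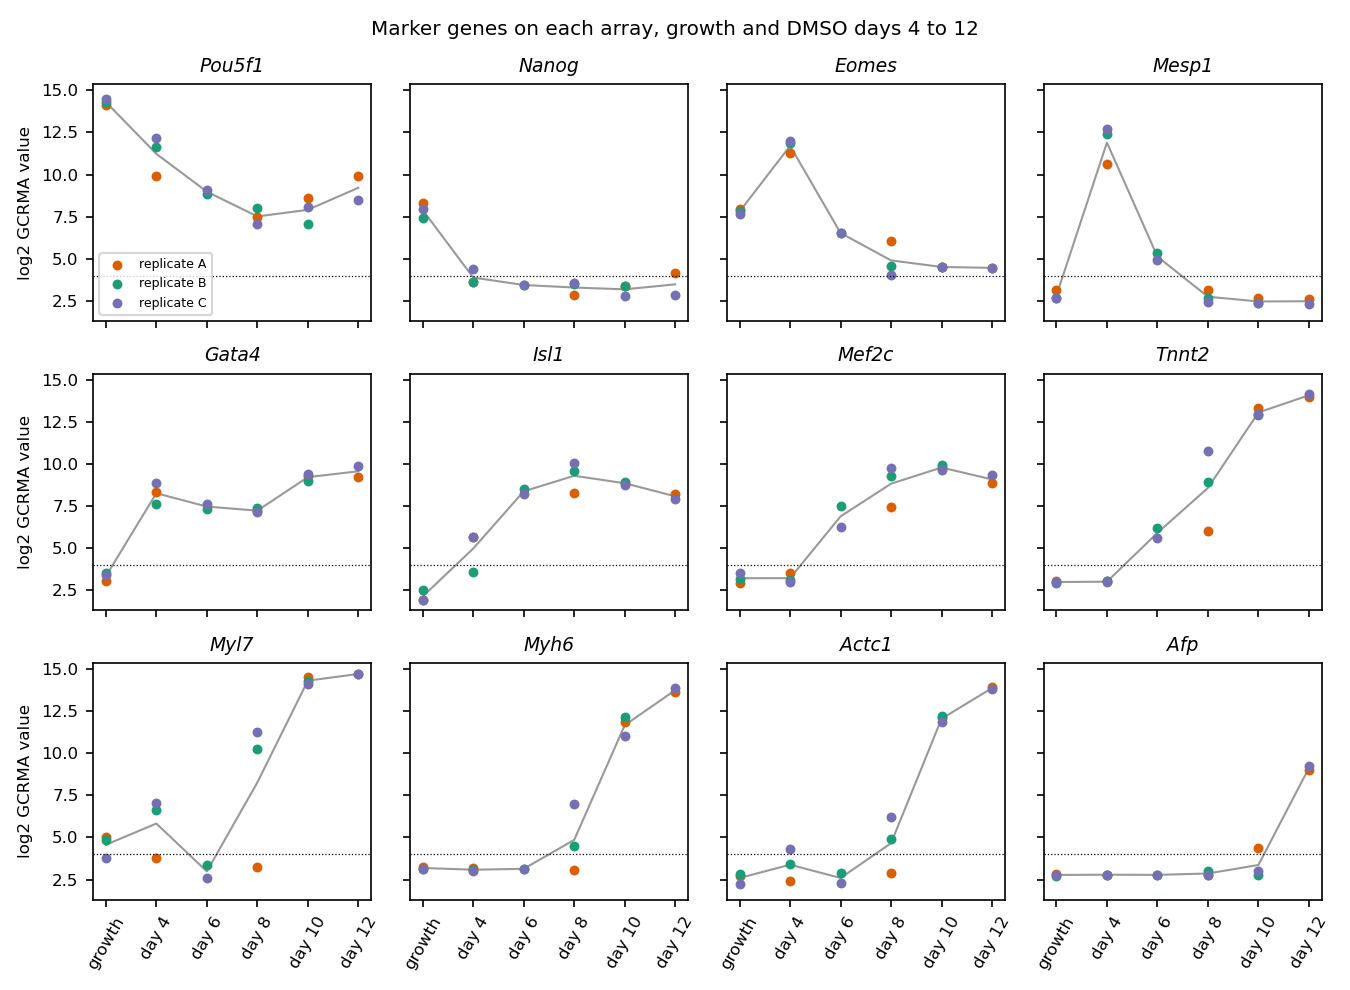
Log2 GCRMA value of 12 marker genes on each of the 16 arrays by group, with points coloured by replicate letter, a line through the group means and a dotted line at the dim cutoff of 4. Mesp1 reaches a mean of 11.89 at day 4 and 2.48 at day 12, and Myh6 goes from 3.08 to 13.73, with day 8 replicate A at 3.07.

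Genes called at 1 day overlapped those called at another. Of the 1442 genes up at day 4 and the 2435 up at day 12, 860 were shared, where 325.06 would be if the calls were independent, and 904 were down at both days against 284.67. Days 10 and 12 shared 1835 rises against 451.52. All days share the 3 growth arrays, which adds to such overlap. In 20 simulations with no change, as many genes per day as were called, taken by t, shared a mean of 725.3 rises and 660.4 falls between days 4 and 12 and 929.1 rises between days 10 and 12. At the thresholds used for calls the same simulations shared a mean of 0 rises and 0 falls between these days. Part of the overlap may come from the shared arrays, but simulations without real change do not measure how much. Between days 4 and 12, 106 genes were called in opposite directions.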

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

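The genes and counts of this part were chosen after the changes against growth were seen. Between days 4 and 12, 38 genes were called higher than growth at day 4, lower than growth at day 12, and lower at day 12 than at day 4, so that their difference between the days was itself tested. They were set apart because their changes against growth have opposite signs. After values under 4 were set to 4, the largest differences between the days were those of Eomes, Vrtn, Axin2, Prtg and Il17rd. Vrtn went from 6.99 in growth to 9.81 at day 4 and was dim at day 12, a fall of at least 5.81 log2 between the days with an adjusted p of 1.91e-08. Etv2, a regulator of blood and endothelial progenitors, went from 4.84 to 7.64 and was dim at day 12, and Axin2, a target of Wnt signalling, from 5.90 to 10.03 and 3.88.

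The opposite course, lower than growth at day 4 and higher at day 12, was seen in 68 genes. Their called rise between the days was likewise nearly fixed by this choice. After values under 4 were set to 4, the largest rises between the days were those of Sfrp1, Spon1, Myrf, Tmcc3 and Mfsd6. Genes with smaller rises included the glycolytic enzyme Tpi1, which went from 12.57 in growth to 11.47 and 14.03. The lactate transporter Slc16a3 went from 7.78 to 6.63 and 9.02, and the actin-binding Pfn2 from 9.62 to 8.55 and 11.23. At day 4 Tpi1 fell by 1.11 log2 against growth and Slc16a3 by 1.15, and these calls ended when day 4 replicate B (Tpi1, -0.94) or replicate A or B (Slc16a3, at the least -0.92) was left out. No biological explanation was tested for either set of genes.

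Probe sets that name several genes or none were not used in the comparisons of genes. Of the 2220 that passed the same filter, 946 differed among the 6 groups by the F test. At day 12, 349 were higher and 273 lower than in growth, and 3 differed between days 8 and 6, with day 8 replicate A included. Their transcripts are not named here.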

How the results depend on the processing

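The arrays of letters B and C were fitted after the data were seen, and the other alternatives were planned. Named genes, in 887 pairs of a gene and a comparison, were not followed with all probe sets or with only the groups compared, and 820 pairs were left with the stricter filter and 870 without _x_at and _s_at probe sets. In the other alternatives and in these pairs, no call changed direction. The leave-outs kept 4568 results, ended 260 calls and added 21. Calls ended and added were 54 and 0 with no dim filter, 32 and 4 with values set to the cutoff, 23 and 23 with letters B and C, 14 and 2 with the mean of probe sets, 10 and 2 with the replicate block, 4 and 17 with array weights, 4 and 1 without _x_at and _s_at probe sets, 3 and 1 with the stricter filter, 3 and 1 after quantile normalization, 1 and 0 with a common median, 0 and 3 with the variance trend and 0 and 2 with the adjusted p alone. The counts against growth, of day 12 against day 4 and of the F test stayed within 1.5 times except with all probe sets (4824 at day 4, 4655 at day 6, 5432 at day 8, 6678 at day 10, 7523 at day 12, 5826 for day 12 against day 4 and 10860 for the F test), where more features were tested, and with the adjusted p alone (5203, 4667, 5730 and 6496 at days 4 to 10, and 5590 for day 12 against day 4), which drops the fold threshold. Day 8 against day 6 gave 2 genes and moved most: 1 with no filter on dim probe sets, 1 with a common median, 0 with only the groups compared, 4 with values set to the cutoff, 4 with all probe sets, 8 after quantile normalization, 14 with the replicate block, 752 with array weights and 729 with letters B and C, the last 2 of which weigh down or omit day 8 replicate A. Leaving out 1 array gave 1 (day 8 replicate C) to 613 (day 8 replicate A). Day 10 against day 8 gave 368 with only the groups compared, 1321 with all probe sets and 1710 with the adjusted p alone, against 844. Day 12 against day 10 gave 142 with the stricter filter, 121 with only the groups compared, 512 with all probe sets and 753 with letters B and C, against 331, and 155 (without day 12 replicate C) to 480 (without day 10 replicate A). Day 6 against day 4 gave 415 with only the groups compared, against 662, and 309 (without day 6 replicate C) to 799 (without day 4 replicate A). Apart from fewer or more features or arrays, the cause was not tested. An array left alone in its group was assumed to vary like the other groups. Of 61 called pairs of a list and a day, 0 were called with an estimated correlation, and leave-outs at the preset correlation gave 59 to 68. With an estimated correlation and without day 8 replicate A, the cell cycle and cardiac factor lists were called at days 8 and 10. The sarcomere and extracellular matrix lists were then called at day 10.

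After group means were removed, the correlation across genes over the 35 pairs of same-letter arrays of different groups ran from -0.21 to 0.32, with 13 over 0.1 and a median of 0.063 against -0.033 for different letters, and the best match in other groups had the same letter for 12 of 16 arrays. With the replicate block 4578 genes were called at day 12, of which 4464 were among the 4524, 677 from day 4 to 6 (609 of the 662) and 306 from day 10 to 12 (277 of the 331). The named calls that ended with the block were those of Myh6 at day 8, Nebl, Pou5f1 and Ryr2 from day 4 to 6, and Cthrc1, Myl9, Spint2, Tbx18, Tcf7l2 and Wnt11 from day 10 to 12 (adjusted p 0.053 to 0.0825), and the Wnt list at day 6 (adjusted p = 0.0558). Hybridization controls were lower on letter A than on the other letters in 5 of 5 groups, by a mean of -0.84 log2 (exact within-group permutation p = 0.0062, 0.0417 after adjustment over 15 tests). This comparison of letters was not planned. Signal over background limits the dim genes, for which folds are lower bounds.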

Other observations

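The tests of this part were chosen after the results were seen, except the 4 counts of other splits of the arrays. Some genes were highest between days 4 and 8. Tdo2, a tryptophan oxygenase, was at 2.51 in growth, 7.53 at day 6, 8.35 at day 8 and 2.59 at day 10. The adhesion gene Igsf11 went from 2.35 at day 4 to 5.39 at day 6, 8.13 at day 8 and 3.63 at day 12. Hand1 peaked at day 6, at 10.57, and was at 6.96 at day 12, while the related Hand2 was at 6.75 at day 6 and 11.94 at day 12. The proto-oncogene Myc was at 7.34 in growth, 10.22 at day 4 and 4.77 at day 10.

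Tnnt1, the slow skeletal troponin T, was the sarcomere gene that fell against growth on each day. It was at 9.61 in growth, 2.75 at day 6 and 6.83 at day 12, and rose between days 10 and 12. Shox2 and Trdn were dim through day 8, at 2.48 and 2.55, and at 9.09 and 8.70 at day 12.

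Day 8 replicate A lay with the day 6 arrays. Between it and these arrays 0 genes were called, against up to 170 for another lone array against its own group (growth replicate A) and 349 for this array against day 8 replicates B and C, which is what a mislabelled sample would give. A swap with a day 6 array is unlikely, since the highest correlation of a day 6 array with day 8 replicates B and C was 0.965, against 0.992 between the day 6 arrays. A difference between letter A and the other letters is also unlikely, since the array's difference from B and C correlated across genes at no more than 0.06 with that of growth, day 4 and day 10, and at 0.11 with that of day 12, which has 1 other array. For a culture that had advanced less by day 8 the same 0 genes decide nothing, since 1 array was set against 2 with the spread taken from the other groups, so it and a wrong label cannot be told apart. Day 6 is the only group without a replicate A.

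Rises made up 94.0% of the genes changed from day 10 to day 12. The share was 86.1% (236 up, 38 down, against 311 and 20) at the lower of 2 other scalings. The deposited values were already normalized by quantiles, and scaling them again cannot show what that first step did. The array normalization therefore stays open as a cause. With the stricter filter the share was 90.8% (129 up, 13 down). This filter keeps genes that are dim at day 10 and bright at day 12. It therefore cannot decide whether dim values near the background are a cause. With values under the cutoff set to the cutoff, the share was 93.5% (287 up, 20 down). Differences below the cutoff are therefore unlikely to account for all of the rises. The share was lowest, 83.4%, without day 12 replicate A. An RNA preparation that differed on day 12 cannot be told apart from the day, because the 18S controls of the lowest day 12 array lay 1.16 log2 above the highest other array. Other cell types may also have appeared by then, although the endoderm and epicardium lists were already called against growth at day 10. Of their members 29.2% (7 of 24) rose from day 10 to day 12, against 2.88% of all genes. These were 6 of 11 epicardium but 1 of 13 endoderm members, and 26.9% of sarcomere members (7 of 26) rose too, and the criterion was tightened after its value was seen, so this stays open.

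Pou5f1 was bright at day 12, at 9.21 (9.94 and 8.49 on the 2 arrays). Its means were lower at days 8 and 10, at 7.51 and 7.91, and the difference of day 12 from day 10 was not called. The day 12 arrays are those with the higher control signals. Undifferentiated cells left in the culture might keep Pou5f1 bright, and would keep other pluripotency genes at a like share of their growth level. Of 7 other members bright in growth, 2, Utf1 (-7.32) and L1td1 (-7.21), fell further than Pou5f1 (-5.09) by over 2 standard errors, and Sox2 (-2.49) fell less. Expression outside such cells was not measured, so the explanation stays open.

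For comparisons of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05. In each, 1 of the 10, the real one, gave as many genes: 2914 at day 4 with at most 2 in another split, 3349 at day 8 with at most 1, 4107 at day 10 with at most 0, and 844 for day 10 against day 8 with at most 1. Every other split mixes the 2 groups, so real differences between them widen the spread and lower its count. The low counts therefore do not measure false calls.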
